A study of Mus musculus with 20 samples.

How the data were processed

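The deposited files hold 1 whole-number count per gene symbol and library, 20 files in all, which the authors deposited without scaling. Per the labels' protocols, cones were isolated by fluorescence-activated sorting, RNA was extracted with Trizol or the Arcturus PicoPure kit, and 150 ng of total RNA went into the ScriptSeq Complete Low Input kit. Libraries were pooled in batches of 4, each batch on 1 lane of a HiSeq 2000, and the labels do not say which extraction or lane each library had. Per the submitters' processing notes, CASAVA 1.8.0 and the mm10 (GRCm38) build were used. The aligner, the counting program, the annotation, the strand setting and the treatment of duplicate reads are not given in the sources used here. Without strand information, reads of antisense or overlapping genes cannot be told apart, and this holds for microRNA hairpins inside longer transcripts. Nothing in the labels says that the 2 replicates of a group came from separate animals. Low counts run without gaps in every file, so the counts were not scaled up and rounded. The variance between the 2 libraries of a group was 1.95 to 24.48 times the sampling variance, so no library used here is a copy of another.

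Each file has 23077 gene symbols, of which 524 had 0 counts everywhere, and 2 unnamed entries with 14 counts in total that were left out. Against GENCODE M21, 21103 symbols matched directly, 1761 through an older symbol and 213 not at all. Symbols are printed as deposited, and coordinates are those of GRCm38. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, limma 3.58.1) with TMM scaling, the filterByExpr filter by group and 1 coefficient for each of the 10 groups. It kept 18354 genes, with a biological coefficient of variation of 0.161. P-values were adjusted by Benjamini and Hochberg, and a gene was called at an adjusted p below 0.05. The averaged comparison is the mean of the 5 KO minus WT differences, and the interaction is an F test of whether the differences vary between ages. Levels are TMM-scaled CPM, and a log2 fold change without a gene name beside it is a median over genes.

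Genes were named by rule, and names of digits plus Rik, Gm plus digits or LOC were passed over outside the lists. In the average these are the 10 higher and 10 lower called genes of smallest p with the same sign at all ages, at each age the 3 higher and 3 lower of smallest p not named before, in the age and interaction comparisons the first 4 each way, and in each list up to 4 members. Dgcr8, Drosha, Dicer1, Opn1sw, Opn1mw, Arr3 and Gnat2 are always reported. Some genes that the rule names are not reported here. A330023F24Rik and Cdkn1a were chosen after their values were seen. The gene lists were cone phototransduction, outer segment structure, photoreceptor cilium and intraflagellar transport, photoreceptor synapse, photoreceptor transcription factors, microRNA pathway, microRNA genes, microRNA host transcripts, reported miR-124 targets, p53 and apoptosis, unfolded protein and integrated stress response, cytosolic heat shock, immediate early genes, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, cholesterol synthesis, interferon response, and retinal stress and gliosis. Marker lists covered rods, Mueller glia, bipolar, amacrine, horizontal and ganglion cells, pigment epithelium, microglia, vessels, astrocytes, erythrocytes and lens. Lists were tested with camera at an assumed correlation of 0.01 between genes, adjusted over all lists of a comparison, and again with the correlation estimated from the data. The test at 0.01 also called lists under rearranged genotype labels, as given in the closing part. Such a call alone therefore does not exclude chance.

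For the seed matches, the log2 fold change of each gene was regressed on the presence of a sequence of 7 bases in its longest annotated 3 prime UTR, with log2 UTR length and GC content as covariates, for all 16384 sequences. UTRs came from the GENCODE M21 annotation and transcripts and covered 90.3% of genes tested. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

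The comparisons, tests, lists, naming rule and the following alternatives were fixed before the data were examined: DESeq2 1.42.0, RLE factors, no filter, a mean CPM of at least 5, a 2-fold threshold, the replicate number as a block, the rod marker score as a covariate, each library left out, only the compared groups fitted, fry and estimated correlation for lists, and 5 versions of the seed test. Upper quartile scaling was not run. Chosen after the data were seen were factors from the 5603 genes with a mean CPM of at least 32, alone and with the filter at 5, the background share as a covariate, replicates summed with ages as pairs, each age left out, and seed tests at each age. They were added because 1419 olfactory and vomeronasal receptor genes, silent in retina, held shares of counts that differed between libraries. The rule for reading 1 of the tests in the closing section, the share of lower genes with a clear level, was also changed after its value was seen, so that its 95% interval had to clear the bound.

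In a self-test on counts simulated with the library sizes, gene means and fitted spread of these libraries, with known changes planted in KO, the averaged comparison recovered 76% of 100 genes changed 2-fold and 51% of 98 changed 1.5-fold, and called 8 unchanged genes of 17010 run. At single ages it recovered 43% to 53% at 2-fold and 19.4% to 29.6% at 1.5-fold. A planted list of 20 genes was called and 0 of 20 random lists were, and, with fold changes shuffled among genes, 20 of 20 planted sequences of 7 bases ranked in the top 1%. Apart from the planted changes, the simulated libraries shared the same mean per gene, without background differences, age effects or correlation between genes. The few false calls therefore do not show how many the real libraries give.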

Results

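RNA was sequenced from mouse cones, the photoreceptors of daylight and colour vision, after fluorescence-activated sorting. The wild type (WT) controls carried the cone-specific D4-Cre driver, and the labels list the tdTomato reporter Ai9 for both genotypes. In the knockout (KO), D4-Cre acted after birth on a conditional allele of Dgcr8, whose protein pairs with the nuclease Drosha to cut microRNA hairpins out of primary transcripts. Both genotypes were taken at P30, P40, P50, P60 and P90 (days after birth), with 2 libraries for each of the 10 groups and 20 libraries in all. Each library held 2.24 to 10.37 M counts (M, mega). Depth differed most at P30, where WT libraries held 2.28 ± 0.057 M counts (SD, n = 2) and KO libraries 8.85 ± 0.453 (SD, n = 2). At P60 the order turned, with 10.1 ± 0.389 M in WT and 7.36 ± 0.891 in KO (SD, n = 2 each). At P40, P50 and P90 the WT means were 3.06, 4.21 and 3.58 M and the KO means 8.36, 6.32 and 5.41 M. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

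Dgcr8 (chromosome 16, 18253948 to 18289246, minus strand, GRCm38) was measured in every library. At P30 it stood at 86.5 ± 7.08 counts per M (CPM) in WT and 56.9 ± 1.56 in KO, and at P40 at 79.1 ± 6.58 and 55.2 ± 3.90 (SD, n = 2 each). At P50 the levels were 80.3 ± 2.50 and 54.3 ± 3.47 CPM, and at P60 91.8 ± 6.60 and 69.2 ± 3.96 (SD, n = 2 each). At these 4 ages both KO libraries lay below both WT libraries. At P90 the WT libraries read 82.0 and 93.9 CPM and the libraries labelled KO 75.5 and 89.4, so the groups overlapped. Averaged over ages the log2 fold change was −0.44 (SE 0.065, adjusted p = 5.57e-08 by edgeR's quasi-likelihood test), with −0.61 at P30 (adjusted p = 0.00113) and −0.10 at P90 (adjusted p = 0.777). The averaged call of Dgcr8 was lost when the 2 libraries of each group were summed and the ages taken as pairs (−0.415) and with the rod marker score as a covariate (−0.498). The deleted exons are not given in the sources used here, so reads from the rest of the gene may remain in KO cells and the gene-level count is a partial check of the labels.

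Averaged over the 5 ages, the genes that rose most clearly in KO included Oxct1, a mitochondrial enzyme of ketone body use (log2 fold change 1.93, SE 0.041, a 3.81-fold rise). Bcat1, the cytosolic branched-chain aminotransferase, rose by 1.56 (SE 0.035), Acsl1, which activates long-chain fatty acids, by 1.57 (SE 0.043) and the secreted chaperone Clu by 1.66 (SE 0.047). Stom (1.74), Ssx2ip (1.71), the LIF receptor gene Lifr (1.58), the Golgi protein gene Golgb1 (1.32), the matrix protein gene Tnc (2.19) and the nuclear RNA Malat1 (0.99) completed the 10 higher genes named by rule. The 10 lower genes were led by Lrtm1 (−1.77, SE 0.042), Lynx1 (−2.10, SE 0.051), a modulator of nicotinic receptors, the secreted Olfm1 (−1.83, SE 0.045) and the short-wavelength opsin gene Opn1sw (−1.02, SE 0.026). Dnahc9 (−1.61), Crb1 of the apical polarity complex (−1.02), the vesicle GTPase gene Rab27b (−1.52), Adcy1 (−0.91), Hspa12a (−1.05) and Fam40b (−1.45) followed. The fitted value of each of these 20 genes had the same sign at all 5 ages, and edgeR's adjusted p ran from 3.73e-28 for Fam40b to 1.21e-47 for Oxct1.

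Of 18354 genes tested, 4045 were higher and 2120 lower in KO averaged over ages (edgeR, Benjamini-Hochberg adjusted p below 0.05), of which 383 and 570 changed at least 2-fold. The split depended on the scaling. With factors from the 5603 genes of at least 32 CPM, a choice made after the data were seen, 2177 genes were higher and 4686 lower, and with RLE factors 3043 and 3171. The scaling on abundant genes moved the median of all genes by −0.22 in the average, by −0.42, −0.39, −0.22, 0.04 and −0.12 at the 5 ages in order, by −0.09 in WT with age and by 0.21 in KO with age. Without P60 the counts were 4508 higher and 5033 lower, and without P40 2388 and 2843. They fell to 1364 and 184 with replicates summed and ages as pairs, and to 899 and 241 with the rod marker score as a covariate. With the log2 share of counts in silent receptor genes as a covariate they were 3368 and 1716. That fit had age and genotype terms without their interaction, so the change does not come from the covariate alone.

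**Figure D1:**
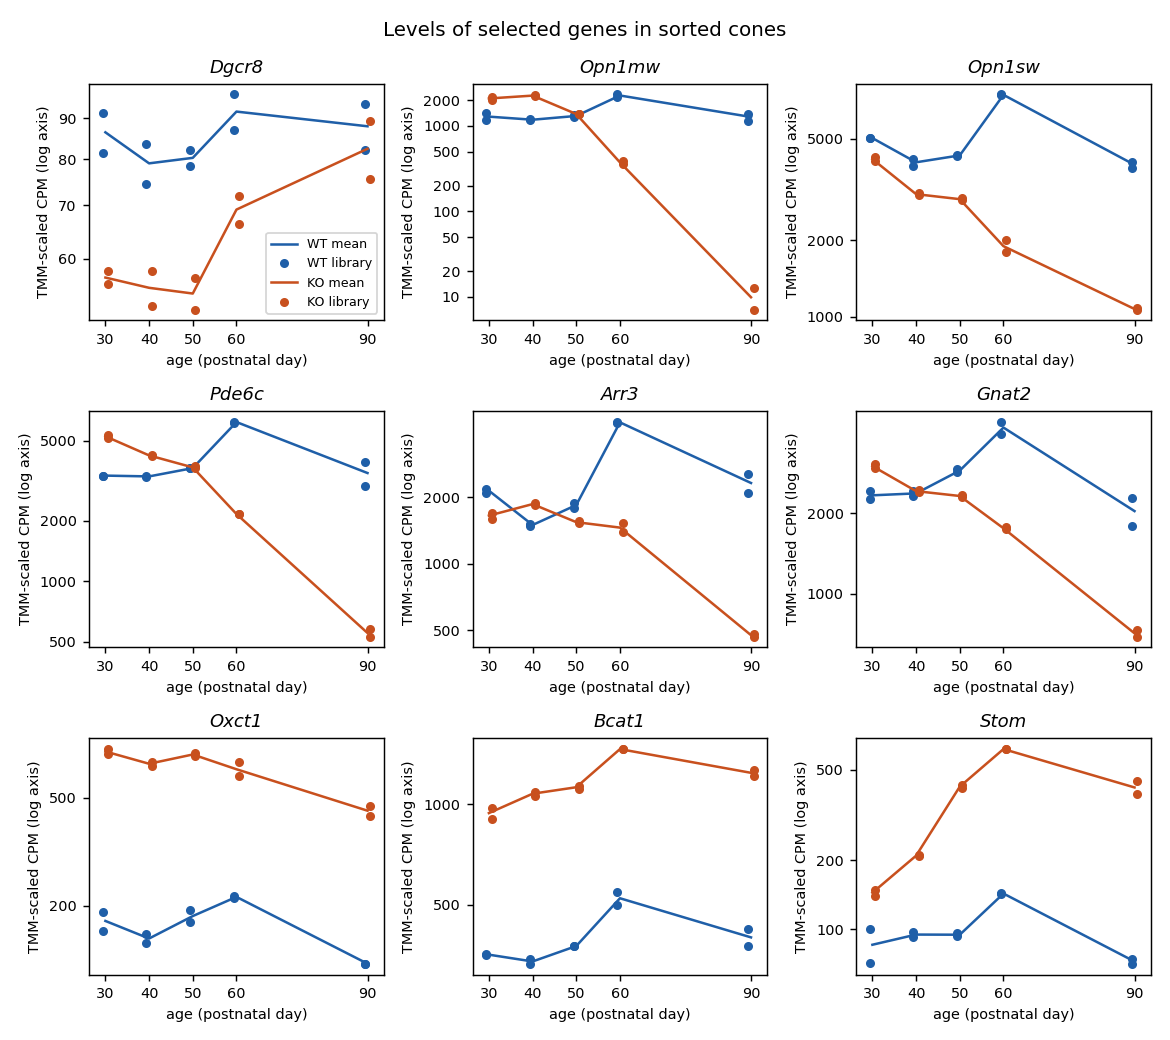
Levels of 9 genes in TMM-scaled CPM (log axis) against age in postnatal days, with a point for each library and lines through the means of WT (blue) and KO (orange), n = 2 per group. Opn1mw in KO went from 2093 CPM at P30 to 9.86 at P90, while Oxct1 in KO stayed above WT at each age; the signs of Gnat2 at P30 and P40, Arr3 at P40, Pde6c at P40 and P50 and Opn1mw at P50 flip when scaled on abundant genes.

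Among the lists fixed before the data were examined, cholesterol synthesis rose as a group, with 15 of 22 members higher and 0 lower over all genes tested, and 15 and 0 adjusted over the list alone (camera adjusted p = 1.72e-09, and adjusted p = 0.00324 with an estimated correlation). Sc4mol rose by 1.30 (SE 0.060), Hmgcs1 by 1.03 (SE 0.049) and Srebf2, which encodes the transcription factor of the pathway, by 1.55 (SE 0.074). The unfolded protein and integrated stress response list had 16 of 21 members higher and 0 lower, and 16 and 0 adjusted over the list alone (camera adjusted p = 2.16e-08, and adjusted p = 0.00732 with an estimated correlation). Its endoplasmic reticulum chaperones Hsp90b1 (0.80, SE 0.033), Hspa5 (0.76, SE 0.033) and Calr (0.60, SE 0.041) were among them, though Hspa5 and Calr had values of −0.25 and −0.24 at P60. In the cytosolic heat shock list 10 of 14 members rose and 0 fell, against 10 and 1 adjusted over the list alone (camera adjusted p = 0.00169, and adjusted p = 0.0294 with an estimated correlation), with Hsp90ab1 at 0.85 (SE 0.041). At P60 the heat shock list had 3 members higher and 7 lower and the unfolded protein list 7 and 7, and neither was called there (camera adjusted p = 0.0671 and 0.843). In the average, scaled on abundant genes of at least 5 mean CPM, the heat shock list had 5 members higher and 3 lower. It was not called there (camera adjusted p = 0.244, with its other settings from 0.00104 to 0.233).

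The microRNA pathway list had 13 of 18 members higher and 2 lower in KO, the same counts adjusted over the list alone (camera adjusted p = 7.40e-06, and adjusted p = 0.00492 with an estimated correlation). Scaled on abundant genes of at least 5 mean CPM, 9 were higher and 4 lower, and the call was lost at adjusted p = 0.165 with an estimated correlation. Dicer1 rose by 0.89 (SE 0.044), and the Argonaute partners Tnrc6b and Tnrc6a by 0.80 (SE 0.036) and 0.69 (SE 0.043). Drosha rose by 0.30 (SE 0.061), and its value was 0.08 when scaled on abundant genes. Of 47 annotated microRNA genes tested, 19 were higher and 2 lower, against 21 and 2 adjusted over the list alone (camera adjusted p = 0.00374, and adjusted p = 0.0249 with an estimated correlation). Under the same alternative 11 of these genes remained, 5 higher and 3 lower, and the call was lost at adjusted p = 0.102 with an estimated correlation. Mir29c rose from 5.49 ± 0.0952 to 42.4 ± 0.370 CPM at P90 (SD, n = 2), and its averaged log2 fold change was 3.16 (SE 0.135); Mir29b-2 rose by 3.80 (SE 0.178) and Mir96 by 3.24 (SE 0.41). A330023F24Rik, which the naming rule passes over for its type of name and which was chosen after its values were seen, carries both miR-29 hairpins in its exons (chromosome 1, 194976375 to 195037904, plus strand, GRCm38) and rose by 2.63 (SE 0.033), the smallest p of all genes tested. Reads over a hairpin cannot be told apart here from reads of the transcript that contains it, so these values do not measure mature microRNAs.

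Immediate early genes rose as a list, with 7 of 21 members higher and 0 lower, unchanged when adjusted over the list alone (camera adjusted p = 0.00744, and adjusted p = 0.034 with an estimated correlation). Egr1 (1.87, SE 0.103), Nr4a1 (1.54, SE 0.099), Jund (1.20, SE 0.095) and Btg2 (0.84, SE 0.043) were the examples with the smallest p. With the rod marker score as a covariate 3 members were higher and the list was not called (camera adjusted p = 0.233; the other alternatives ranged from 0.000256 to 0.0199). Of 19 reported miR-124 targets 11 were higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.00209, and adjusted p = 0.0249 with an estimated correlation), among them the integrin gene Itgb1 (0.94, SE 0.067), Sp1 (0.62), Iqgap1 (0.75) and Cd164 (0.70). Scaled on abundant genes of at least 5 mean CPM, 10 targets were higher and 2 lower, and the call was lost at adjusted p = 0.0799 with an estimated correlation. With the rod marker score as a covariate 5 targets were higher and 1 lower and the list was not called (camera adjusted p = 0.233, with the other alternatives from 0.000814 to 0.0218). Oxidative phosphorylation had 39 of 76 members higher and 1 lower, 41 and 2 adjusted over the list alone (camera adjusted p = 2.05e-05), but this call was lost at adjusted p = 0.162 with an estimated correlation. When scaled on abundant genes of at least 5 mean CPM, that list had 13 members higher and 17 lower. In this list Ndufa4 rose by 0.80 (SE 0.067) and Ndufv2 by 0.48 (SE 0.054).

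Cone phototransduction was the list that fell, with 12 of 21 members lower and 5 higher, against 12 and 6 adjusted over the list alone (camera adjusted p = 2.05e-05). The call was lost at adjusted p = 0.162 with an estimated correlation, and over the other settings camera's adjusted p ran from 1.78e-13 to 0.266. Scaled on abundant genes of at least 5 mean CPM, 19 members were lower and 1 higher (camera adjusted p = 2.97e-10, and adjusted p = 0.00613 with an estimated correlation). Opn1mw, the medium-wavelength opsin gene, fell by 1.58 on the log2 scale (SE 0.042), Opn1sw by 1.02 (SE 0.026), the cone arrestin gene Arr3 by 0.84 (SE 0.031) and the cone phosphodiesterase gene Pde6c by 0.63 (SE 0.029). The cone transducin gene Gnat2 fell by 0.54 (SE 0.031).

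The remaining functional lists were not called in the average. Outer segment structure had 5 members higher and 3 lower, the cilium and intraflagellar transport list 16 and 6, the photoreceptor synapse list 10 and 7, photoreceptor transcription factors 8 and 3 and the microRNA host transcripts 4 and 2. Adjusted over the list alone these were 5 and 3, 16 and 7, 11 and 7, 8 and 5 and 4 and 2. Scaled on abundant genes of at least 5 mean CPM, the first 4 turned to 3 and 13, 5 and 17, 5 and 13, and 3 and 7, and the synapse list was then called lower (camera adjusted p = 0.0463, lost at adjusted p = 0.102 with an estimated correlation). Glycolysis had 6 members higher and 7 lower, cytosolic ribosomal proteins 15 and 2, p53 and apoptosis 6 and 2, interferon response 0 and 3 and retinal stress and gliosis 2 and 0; adjusted over the list alone these were 7 and 9, 14 and 2, 6 and 2, 0 and 1, and 2 and 0. Scaled on abundant genes of at least 5 mean CPM, the ribosomal list turned to 6 higher and 21 lower, glycolysis to 4 and 11, the host transcripts to 3 and 4, p53 and apoptosis to 3 and 2, interferon response to 0 and 2 and the stress list to 1 and 1. Ldha rose by 0.60 (SE 0.036) and Hk2 fell by 0.39 (SE 0.036), and within the stress list Stat3 rose by 1.28 (SE 0.059). The transcription factor gene Crx rose by 0.46 (SE 0.034).

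Among markers of other cell types, those of rods were higher averaged over ages, with 7 of 13 higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.00374). The call was lost at adjusted p = 0.117 with an estimated correlation, and scaled on abundant genes of at least 5 mean CPM the counts were 3 higher and 6 lower. Pde6a rose by 0.96 (SE 0.031) and the rod arrestin gene Sag fell by 0.27 (SE 0.027). Markers of Mueller glia (2 higher, 1 lower), bipolar (0 and 4), amacrine (1 and 0), horizontal (2 and 1) and ganglion cells (2 and 2) were not called as lists. Scaled on abundant genes of at least 5 mean CPM, 9 of 9 bipolar markers were lower and the list was called (camera adjusted p = 0.0233, lost at adjusted p = 0.167 with an estimated correlation; its other settings ranged from 0.0131 to 0.233), and Mueller glia markers turned to 1 higher and 6 lower. Nor were those of pigment epithelium, microglia, vessels and astrocytes, with 0 members changed, the erythrocyte marker Alas2, or lens, with 2 higher and 0 lower, though lens was called under the abundant scaling of all genes (camera adjusted p = 0.0144, with other settings up to 0.481).

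At P30, Mtap2 (1.05, SE 0.071) and Pde6a (1.00, SE 0.069) were higher genes named by rule, and Ttn (−2.35, SE 0.152), Ugt1a6a (−3.72, SE 0.323) and Sfi1 (−1.64, SE 0.147) the lower. Oxidative phosphorylation had 61 of 76 members higher and 0 lower, and 64 and 0 adjusted over the list alone (camera adjusted p = 4.78e-17, and adjusted p = 0.0115 with an estimated correlation), with 22 and 0 under the abundant scaling. Cytosolic ribosomal proteins had 44 of 79 members higher and 0 lower, 47 and 0 adjusted over the list alone (camera adjusted p = 7.28e-10, and adjusted p = 0.00403 with an estimated correlation), with 15 and 0 under the abundant scaling. Cone phototransduction had 17 of 21 members higher and 2 lower, 18 and 2 adjusted over the list alone (camera adjusted p = 4.58e-09, and adjusted p = 0.0398 with an estimated correlation), but 7 and 4 and no call under the abundant scaling. List counts at single ages under that scaling use genes of at least 5 mean CPM. Rod markers rose too, with 13 of 13 higher, also when adjusted over the list alone (camera adjusted p = 9.15e-10, and adjusted p = 0.0086 with an estimated correlation), and 3 and 0 under the abundant scaling, where the call was lost at adjusted p = 0.147 with an estimated correlation. In total 3682 genes were higher and 2527 lower, and under the abundant scaling 962 and 4362. At this age the 384 silent olfactory and vomeronasal receptor genes tested had a median of −3.33, and all 1419 such genes held 0.158% of WT and 0.016% of KO counts. Leaving out 1 library brought the lower genes to 1583 (WT replicate 1), 1435 (KO replicate 1) or 1087 (KO replicate 2).

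At P40, Nptx1, a neuronal pentraxin gene (1.98, SE 0.090), Olfr1372-ps1 (2.27, SE 0.125) and Xist (5.82, SE 0.134) were higher. Fabp7 (−2.58, SE 0.282), Ip6k2 (−0.71, SE 0.096) and Tmsb10 (−0.96, SE 0.134) were lower. Xist is transcribed from the inactive X chromosome, and its level, 11.4 ± 0.168 CPM in WT and 642 ± 14.3 in KO (SD, n = 2), depends on the sex of the animals, which the labels do not give. The lens markers rose as a list, with 4 of 5 members higher and 0 lower, 5 and 0 adjusted over the list alone (camera adjusted p = 5.04e-05, and adjusted p = 0.00982 with an estimated correlation); Cryaa had 756 and 736 counts in the KO libraries and 0 and 2 in WT. The unfolded protein and integrated stress response list had 13 of 21 members higher and 0 lower, 15 and 0 adjusted over the list alone (camera adjusted p = 6.24e-08, and adjusted p = 0.00982 with an estimated correlation), with Hspa5 at 1.32, and 5 and 0 under the abundant scaling. In total 2896 genes were higher and 573 lower, against 855 and 1761 under the abundant scaling and 1529 and 954 with RLE. The lower genes numbered 4163 with only the compared groups fitted. Under the abundant scaling rod markers had 10 of 13 lower and 1 higher, where the planned scaling gave 1 and 1. The receptor genes had a median of −1.93 here. Leaving out a library brought the lower genes to 217 or 194 (WT replicates 1 and 2) and 159 or 168 (KO replicates 1 and 2).

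At P50, Plekhb1 (1.23, SE 0.068), the copper transporter gene Slc31a1 (2.31, SE 0.136) and Parvb (2.30, SE 0.139) were higher. The phospholipase gene Plcz1 (−1.83, SE 0.159), the potassium channel subunit gene Kcne2 (−1.01, SE 0.090) and Gnb1, a transducin beta subunit gene of rods (−0.83, SE 0.077), were lower. Rod markers fell as a list, with 9 of 13 lower and 1 higher, 10 and 1 adjusted over the list alone (camera adjusted p = 1.96e-08, and adjusted p = 0.00951 with an estimated correlation). Mueller glia markers fell as well, with 9 of 10 lower and 1, Clu, higher, the same counts adjusted over the list alone (camera adjusted p = 0.000123, and adjusted p = 0.00956 with an estimated correlation). Cone phototransduction had 8 of 21 members lower and 2 higher, 8 and 3 adjusted over the list alone (camera adjusted p = 0.042, lost at adjusted p = 0.46 with an estimated correlation), but 12 and 1 under the abundant scaling, kept at adjusted p = 0.0147 with an estimated correlation. Egr1 was higher by 3.44, and 7 of 21 immediate early genes rose with 0 lower, the same counts adjusted over the list alone (camera adjusted p = 0.000987, and adjusted p = 0.0113 with an estimated correlation). In total 2136 genes were higher and 745 lower, and 1207 and 1582 under the abundant scaling. The receptor genes had a median of −0.41. Leaving out a library brought the lower genes to 447 or 401 (WT replicates 1 and 2) and 396 or 370 (KO replicates 1 and 2).

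At P60, cone phototransduction had 19 of 21 members lower and 1 higher, the same counts adjusted over the list alone (camera adjusted p = 1.63e-27, and adjusted p = 0.0108 with an estimated correlation), and 19 and 1 under the abundant scaling too. Opn1mw stood at 2269 ± 96.9 CPM in WT and 374 ± 19.2 in KO, and Opn1sw at 7431 ± 44.0 and 1895 ± 141 (SD, n = 2 each). The WT levels of both were the highest of the 5 ages. Fam19a3 (−2.27, SE 0.094), Opn1mw (−2.60, SE 0.087) and Pde6c (−1.52, SE 0.067) were the lower genes named by rule, and Fkbp9 (5.59, SE 0.242), Ankrd52 (2.97, SE 0.151) and Zdbf2 (3.40, SE 0.173) the higher. Markers of Mueller glia (8 of 10 higher, 0 lower; 9 and 0 adjusted over the list alone), amacrine cells (7 of 11, 0 lower; 8 and 0) and rods (9 of 13, 3 lower; 10 and 3) were called higher, at camera adjusted p = 3.62e-05, 3.25e-05 and 0.000145, and adjusted p = 0.0128, 0.0176 and 0.0388 with an estimated correlation. Under the abundant scaling the rod call was lost at adjusted p = 0.0585 with an estimated correlation. The 384 receptor genes tested turned as well, to a median of 2.21, and all 1419 held 0.002% of WT and 0.019% of KO counts. In total 4087 genes were higher and 2431 lower, and 2596 were higher without WT replicate 1. Among genes with a mean CPM of at least 5 in the same test, 2342 were higher and 2317 lower.

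At P90, Opn1mw fell from 1271 ± 169 CPM in WT to 9.86 ± 3.93 in the libraries labelled KO (SD, n = 2 each), a log2 fold change of −7.00 (SE 0.124), and Opn1sw from 3950 ± 153 to 1074 ± 7.59 (−1.88, SE 0.059). Pde6c (−2.64, SE 0.070), Arr3 (−2.29, SE 0.072), Gnat2 (−1.52, SE 0.070), Kcne2 (−4.07, SE 0.106), Plcz1 (−4.28, SE 0.232), Fam19a3 (−3.74, SE 0.106), Olfm1 (−3.24, SE 0.111) and the junction protein gene Jam3 (−2.66, SE 0.125) were lower as well. Cone phototransduction had 16 of 21 members lower and 2 higher, 17 and 2 adjusted over the list alone (camera adjusted p = 1.55e-26, and adjusted p = 0.00309 with an estimated correlation). The photoreceptor synapse list had 12 of 21 members lower and 3 higher, 12 and 4 adjusted over the list alone (camera adjusted p = 0.000404, lost at adjusted p = 0.0649 with an estimated correlation). Under the abundant scaling it had 13 lower and 3 higher, and the call was kept at adjusted p = 0.00692 with an estimated correlation.

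Tc2n (3.03, SE 0.140), Hook3 (1.83, SE 0.086) and Trp53inp1 (2.17, SE 0.113), a p53 target, were the higher genes named by rule at P90. The p53 and apoptosis list had 8 of 21 members higher and 1 lower, 10 and 1 adjusted over the list alone (camera adjusted p = 0.00243, and adjusted p = 0.0154 with an estimated correlation). Ccng1 rose by 1.23 (SE 0.104), and Cdkn1a, the p21 gene, chosen after its values were seen, went from 0.637 ± 0.559 to 52.4 ± 2.61 CPM (SD, n = 2 each; adjusted p = 3.25e-12 by edgeR). Cholesterol synthesis had 14 of 22 members higher and 0 lower, unchanged when adjusted over the list alone (camera adjusted p = 4.28e-14, and adjusted p = 0.000679 with an estimated correlation), with Sc4mol at 2.17 (SE 0.137). Reported miR-124 targets had 10 of 19 higher and 2 lower, 11 and 2 adjusted over the list alone (camera adjusted p = 3.26e-06, and adjusted p = 0.00309 with an estimated correlation), with Cd164 at 1.79 (SE 0.157) and Itgb1 at 1.51 (SE 0.151). Egr1 rose by 3.06 (SE 0.219) and Jund by 2.13 (SE 0.224), with 6 of 21 immediate early genes higher and 1 lower, 7 and 1 adjusted over the list alone (camera adjusted p = 5.19e-06, and adjusted p = 0.00309 with an estimated correlation).

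Rod markers at P90 had 10 of 13 members higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 3.26e-06, and adjusted p = 0.0125 with an estimated correlation), with Nr2e3 at 1.71 (SE 0.129). Under the abundant scaling 9 were higher and 2 lower, and the call was lost at adjusted p = 0.0876 with an estimated correlation. Bipolar cell markers had 6 of 9 lower and 0 higher, 9 and 0 adjusted over the list alone (camera adjusted p = 3.26e-06, and adjusted p = 0.00577 with an estimated correlation), with Vsx1 at −2.06 (SE 0.357) and Pcp2 at −1.31 (SE 0.270). In total 1851 genes were higher and 1164 lower at P90, and 1385 and 1706 under the abundant scaling. The receptor genes had a median of −1.05. Leaving out a library brought the lower genes to 733 (WT replicate 2) or 772 (KO replicate 1).

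The genotype effect differed between ages for 6825 genes (edgeR's quasi-likelihood F test, Benjamini-Hochberg). Opn1mw had the smallest p, with a KO minus WT log2 difference of 0.71 at P30, 0.94 at P40, 0.07 at P50, −2.60 at P60 and −7.00 at P90 (adjusted p = 1.59e-52 for the interaction); its P50 value is −0.14 under the abundant scaling. Pde6c (adjusted p = 6.58e-42) and Fam19a3 (adjusted p = 5.75e-39) had P90 minus P30 differences of −3.29 and −3.90; under the abundant scaling the sign of Pde6c flips to lower at P40 (−0.04) and P50 (−0.20), and that of Fam19a3 at P30 (−0.26). Over 10 phototransduction genes taken as cone-specific the median was 0.48, 0.33, 0.02, −1.21 and −1.47 at the 5 ages in order, and 0.06, −0.06, −0.19, −1.17 and −1.59 under the abundant scaling. Across genes, which are not independent replicates, the fold changes of pairs of ages correlated at Pearson r from −0.42 (P30 with P60) to 0.63 (P30 with P40) over all genes, with Spearman coefficients of −0.36 and 0.74. Among the 5603 abundant genes r ran from 0.25 (P30 with P60) to 0.84 (P40 with P50). In all, 618 genes were higher and 32 lower at all 5 ages, while 2262 were called higher at 1 age and lower at another. P40 and P50 shared 1791 higher genes where independent lists would share 337, and P60 and P90 shared 790 lower genes where independent lists would share 154. These overlaps and the counts over all 5 ages use the planned scaling and were not recomputed. The abundant scaling moved the median of all genes by −0.39 at P40 and −0.22 at P50. Under it fewer than 1791 genes were higher at either age, so that overlap cannot hold there.

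In WT, P90 differed from P30 by 462 higher and 135 lower genes. Gnb1 rose by 0.66 (SE 0.080) and Mll2 by 0.88 (SE 0.107), while Snora74a fell by 1.28 (SE 0.125) and its host Snhg4 by 1.23 (SE 0.122). Snora74a and Snhg4 had nearly the same counts, 1205 and 1236 in WT P30 replicate 1 and 527 and 565 in WT P90 replicate 1. They may largely be the same reads and are not separate results. Xist rose by 1.49 (SE 0.091) and the Y-linked Eif2s3y and Uty fell by 1.32 (SE 0.163) and 1.08 (SE 0.141). The levels of Xist, Eif2s3y and Uty depend on the sex of the animals, which the labels do not give. Age and sex therefore cannot be told apart for them. The counts were 246 and 256 under the abundant scaling, 6 and 5 when only these 2 groups were fitted, and 213 and 72 or 747 and 205 without WT P30 replicate 1 or 2; without WT P90 replicate 1, 80 were lower. In KO, 1877 genes were higher and 2910 lower at P90 than at P30, and 2975 and 1844 under the abundant scaling. Opn1mw fell by 7.72 on the log2 scale (SE 0.125), Kcne2 by 4.71 (SE 0.108), Plcz1 by 4.99 (SE 0.222) and Rab27b by 2.90 (SE 0.143). The higher genes numbered 1039 without KO P30 replicate 2 and 1215 without KO P90 replicate 1.

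Genes whose 3 prime UTR holds a match to a microRNA seed were compared with the other genes for all 16384 sequences of 7 bases, over 16569 genes with an annotated UTR. Matches of 5 of 12 families known from the retina ranked in the top 1% for a higher level in KO averaged over ages. These were miR-30 (rank 44, coefficient 0.09 log2, SE 0.015), miR-124 (rank 57, 0.08, SE 0.015), miR-182 (rank 101), miR-183 (rank 158) and miR-96 (rank 163). The last 3 are made from 1 cluster that sensory cells express. Their matches (TTGCCAA, GTGCCAT and GTGCCAA) and that of miR-124 (GTGCCTT) are alike in sequence, so their ranks may not be independent. The match of miR-125 ranked 15581, near the other end. Of 4 comparison families (miR-122, miR-1, miR-142-3p and miR-375) 0 ranked there. The 8 highest ranks went to T-rich sequences, led by TTTTTTA with a coefficient of 0.12, so the seed matches were not the sequences with the strongest relation. GTTTACA (rank 14) overlaps the miR-30 match TGTTTAC, and TGCCTTA (rank 16) overlaps the miR-124 match. Both ranked above the matches they overlap. Without the adjustment for UTR length and GC content 1 family remained in the top 1%, and with the shortest UTR of each gene 3 did.

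Fold changes at each age, an alternative chosen after the data were seen, gave the miR-124 match among 10471 genes with a mean CPM of at least 5 the rank 7895 at P30, 513 at P40, 4 at P50, 2 at P60 and 1 at P90. Its coefficient was 0.00 at P30 (SE 0.019), 0.04 at P40, 0.10 at P50, 0.18 at P60 and 0.20 at P90 (SE 0.018). Over all 16569 genes its ranks were 5254, 1804, 686, 2864 and 1, with a coefficient of 0.05 at P60 (SE 0.046) and 0.19 at P90 (SE 0.024), so only the P90 rank was alike in both sets. The comparison family miR-142-3p also reached the top 1% in the smaller set, at P60 (rank 132). The miR-182 and miR-96 matches ranked 17 and 18 at P90 in the 10471 genes, with coefficients of 0.09 (SE 0.019) and 0.10 (SE 0.021). These coefficients compare genes within libraries, and genes are not replicates.

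**Figure D2:**
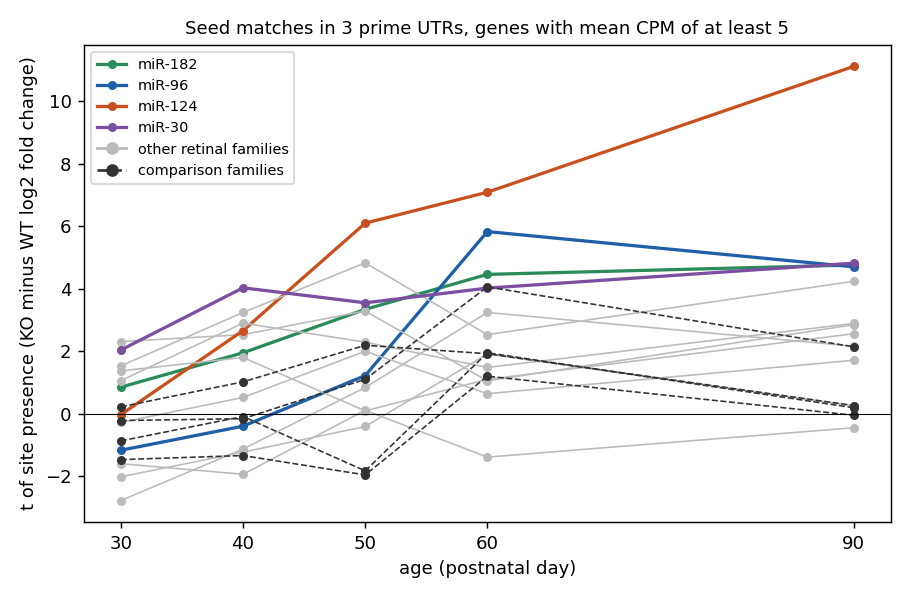
The t of the seed match coefficient (KO minus WT log2 fold change of genes with the match, vertical axis) at each age in postnatal days, for 12 retinal families (solid lines, 4 coloured) and 4 comparison families (dashed), over 10471 genes. The miR-124 line goes from −0.03 at P30 to 11.1 at P90; over all genes tested it is 1.20 at P30, 1.04 at P60 and 8.25 at P90.

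**Figure D3:**
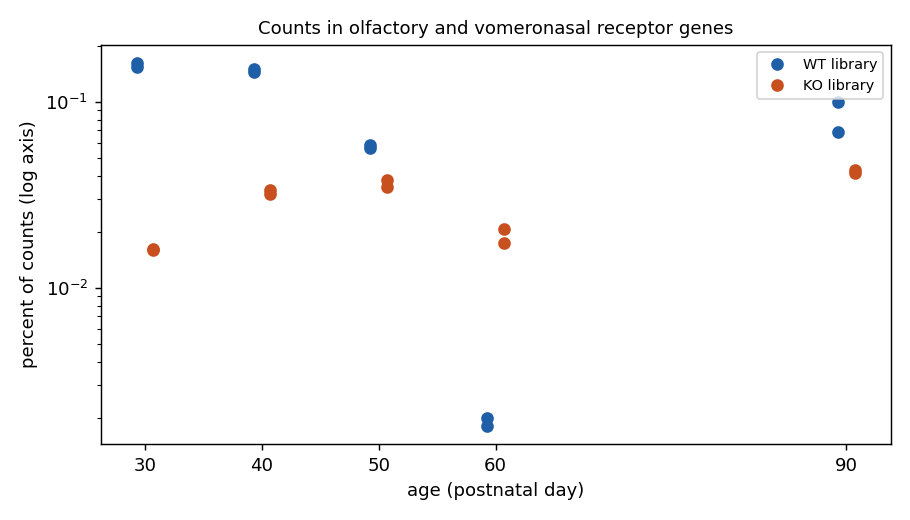
Percent of each library's counts in 1419 olfactory and vomeronasal receptor genes (log axis) against age in postnatal days, with a point for each of the 20 libraries. WT means run from 0.158% at P30 to 0.002% at P60, and KO means from 0.016% at P30 to 0.042% at P90.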

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

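The tests of explanations weighed here were chosen after the result was seen, and the interaction test was planned. Each gene below was picked out because its genotype effect differed between ages, with the value being the KO minus WT log2 fold change at P90 minus that at P30. Opn1mw had −7.70 (edgeR's interaction test, adjusted p = 1.59e-52), Pde6c −3.29 (adjusted p = 6.58e-42) and Fam19a3 −3.90 (adjusted p = 5.75e-39). Xist had −4.24 (adjusted p = 7.43e-51) and the Y-linked Eif2s3y 3.47 (adjusted p = 3.33e-20), moving in opposite directions. Ttn had 1.71 (adjusted p = 7.30e-29), Gnb1 0.10 (adjusted p = 4.97e-23) and Snhg11 0.21 (adjusted p = 1.00e-20), and for these 3 the largest value was at P60, where Ttn was at 3.63, Snhg11 at 2.18 and Gnb1 at 1.12.

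Ttn belongs to a wider pattern, the genes lower in KO at P30 and higher at P60. The 2317 genes at least 2-fold lower at P30 had a median of 2.21 at P60, the direction of the silent receptor genes there. Background reads that differ between libraries could give this. Receptor genes were not left out of the 2317, so part of the likeness may be built in. Of the 2317 genes 24.1% (95% interval 22.4% to 25.9%, which treats genes as independent) had a mean CPM of at least 5. A mean over all libraries also holds background reads. This test therefore cannot tell whether genes the sorted cells express at a clear level also take part. The receptor share was 0.158% in WT and 0.016% in KO at P30, and 0.002% and 0.019% at P60. Reads from genomic DNA and small-input amplification are candidate sources that were not tested.

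Opn1mw and Pde6c belong to the fall of cone phototransduction genes in KO. If the KO libraries only held a smaller share of cone RNA, the 10 genes taken as cone-specific should fall by like amounts. At P90 they spanned 7.21 log2 units, from −7.00 for Opn1mw to 0.21 for Gnb3, with Gngt2 next at −0.06. The wide span argues against a smaller share as the whole cause, though whether each gene is read only in cones was not tested. The median of these genes was −1.21 at P60, where WT had the fewest background reads. A larger background share in KO would itself lower them there, so the P60 value alone cannot tell whether background takes part. At P90 the receptor share was larger in WT (0.084%) than in KO (0.042%), and their median was −1.47. This argues against a larger background share in KO as the cause of the fall at P90. A change in transcription within surviving cones and a loss of the cones with most Opn1mw could each give the fall, and nothing here separates them.

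In KO, Xist went from 993 CPM at P30 to 148 at P90 and Eif2s3y from 30.2 to 133.4. Sex is not given in the labels and was not in the fit.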

How the results depend on the processing

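WT libraries at P30 held 2.28 M (mega) counts and those of WT at P60 10.1 M, so genes with few reads are measured unevenly, and with 2 libraries per group a change of 1.5-fold at 1 age was recovered in 19.4% to 29.6% of planted genes. Unless the construction shows it, the cause was not tested for any value below. Of the other named values, 2237 stayed the same over the settings that keep all libraries, 170 were weaker and 14 stronger. A further 13 reversed in sign and are given below. With 1 library left out 3848 stayed the same, 48 were weaker, 3 stronger and 1 reversed.

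A threshold of 2-fold called fewer genes by construction. Averaged over ages it left 383 higher and 570 lower in place of 4045 and 2120, with 576 higher at P30, 456 higher at P40, 481 higher and 282 lower at P50, 731 lower at P60 and 534 and 426 at P90. The interaction had 2926 in place of 6825, WT with age 54 higher and 38 lower, and KO with age 1021 and 867.

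RLE factors gave 1836 genes higher at P30 in place of 3682 and 1529 higher and 954 lower at P40 in place of 2896 and 573. DESeq2 gave 3465 lower genes in the average, 1804 higher and 3889 lower at P30, 1571 and 1317 at P40 and 257 lower with age in WT in place of 135. The cause was not tested.

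With only genes of a mean CPM of at least 5 fewer genes were tested and the factors came from other genes. The average then had 2452 higher and 3518 lower, P30 1320 and 1641, and P40 1160 and 1216. P50 had 1464 lower, P60 2568 higher, P90 1824 lower, the interaction 4058 and WT with age 243 lower.

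The rod marker score as a covariate draws its slope only from differences between replicates, so it is imprecise by construction. The average had 899 higher and 241 lower, P30 91 and 14, P50 645 and 142, P60 354 and 321 and P90 289 and 250. WT with age had 2 higher and 5 lower and KO with age 571 and 1408. In the average Impg1 reversed to −0.165, Neurod1 to −0.076, Mir3078 to −0.01, Trp53 to −0.096, Rpl13a to −0.007, the rod markers Nr2e3 and Reep6 to −0.131 and −0.277 and Sncg to −0.56. Dgcr8 no longer passed (adjusted p = 0.234 by edgeR) though its value of −0.498 was not smaller, and 4 lists were called higher in place of 8, without cytosolic heat shock, oxidative phosphorylation, immediate early genes and reported miR-124 targets.

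With only the compared groups fitted, P30 had 1988 higher, P40 4163 lower in place of 573, P50 1475 lower, P60 2110 higher and WT with age 6 higher and 5 lower; the spread then comes from 4 libraries.

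The settings in this paragraph and the next were chosen after seeing the data. Scaling on abundant genes gave 2177 higher and 4686 lower in the average, 962 and 4362 at P30, 855 and 1761 at P40 and 1207 and 1582 at P50. WT with age had 246 and 256 and KO with age 2975 and 1844, and 2 lists were lower in place of 1. The median of the synapse list reversed from 0.095 to −0.126. With the filter at 5 mean CPM added, the average had 2185 and 3983, P30 913 higher, P40 923 and 1652, P50 1284 and 1723, P60 2650 higher, P90 1828 lower, the interaction 4004 and WT with age 278 and 299.

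Summing the replicates and pairing by age left 5 pairs, with 1364 higher and 184 lower, Dgcr8 at −0.415 no longer passing and 0 lists lower, beside 4041 and 1978 with the replicate number as a block. Without P40 the average had 2388 higher. Without P60 it had 5033 lower, with Vim reversed in sign to −0.033, Kdr to −0.22 and Flt1 to −0.444. Without P90 Cabp5 reversed to 0.044.

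Among tests of lists, camera with an estimated correlation called 0 lists lower and 7 higher, and fry, a self-contained rotation test, 17 higher and 2 lower in place of 8 and 1. For the seeds, the unadjusted test left 1 family in the top 1% and the shortest UTR 3, in place of 5. Counting only matches followed by an A gave 7.

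The replicate number as a block kept every count and list in its class. The average had 4041 higher and 1978 lower, P30 3638 and 2065, the interaction 6200, Dgcr8 was at −0.438 and 4 seed families stayed in the top 1%. Across genes, the correlation of deviations between same-numbered WT and KO libraries was −0.007 to 0.017, so no shared deviation was seen. This cannot tell whether same-numbered libraries were processed together, which the labels do not say.

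With each library left out in turn, the average had 3887 to 4262 genes higher and 1786 to 2360 lower and the interaction 5970 to 7515. P30 had 1087 to 3029 lower, P40 159 to 760 lower, P50 370 to 856 lower, P60 2596 to 4275 higher and P90 733 to 1269 lower. WT with age had 213 to 747 higher and 72 to 205 lower, and KO with age 1039 to 2057 higher. Dgcr8 ranged from −0.455 to −0.405, and Gnb1 in the interaction from −0.019, without WT P30 replicate 2, to 0.20.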

Other observations

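All tests in this part that bear on microRNA seeds and hosts were chosen after the result was seen, and the tests with rearranged genotype labels were fixed before. Malat1, a nuclear RNA, held 4.93% of WT counts and 6.88% of KO counts at P30, and 4.84% and 12.0% at P90. The Y-linked Eif2s3y stood between 30.2 and 133.4 CPM over the 10 groups and Xist between 11.4 and 1769 CPM, with both present in every group. Mir17hg, the host of the miR-17 cluster, was higher in KO by 1.45 averaged over ages.

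Transcripts that carry an annotated microRNA hairpin were taken as a group. Of 123 with the hairpin in an exon 45 were higher and 8 lower in KO, and their median of 0.14 lay above 98.09% of 10000 random lists matched on expression. Of 453 with the hairpin in an intron 164 were higher and 51 lower, with a median of 0.13 above 99.97% of such lists. Both values are consistent with a rise of host transcripts relative to other genes, and do not show that an uncut hairpin is the cause. The medians are −0.08 and −0.09 when scaled on abundant genes, which moves genes in general by −0.22, so this change of sign does not bear on the rise relative to other genes. The counts do not separate introns from exons.

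Genes with a miR-124 match were higher in KO at P90, with t of 8.25 over all genes tested. The highest t among 209 other orders of the same 7 bases was 5.17, but the match drew notice by ranking 1 of all 16384 sequences, so no other order could be higher and this test cannot tell whether base composition takes part. Mueller glia, which lack this microRNA, could raise its targets by admixture, but their markers had a median of 0.302 at P90 and were not called (camera adjusted p = 0.0946), so this test cannot tell.

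Genotype labels were rearranged within ages in 50 ways, counting the real one. The real labels called 6165 genes and the highest other arrangement 4557, with 1 of 50 reaching the real value. For seed families in the top 1% the real value was 5 and the highest other 3, with 1 of 50 reaching it. These arrangements split the 2 libraries of a group, which may be technical repeats, and that alone raises the spread, so chance cannot be excluded by them for genes or for seed families. For lists the real value was 9 and the highest other 14, with 14 of 50 arrangements reaching it, so chance cannot be excluded for the number of lists. Among arrangements that exchanged 5 libraries of each genotype, 1 called 0 genes but 8 lists, and others called 0 lists. A camera call at the assumed correlation therefore does not by itself exclude chance for a list. The arrangements were not run with an estimated correlation. When both libraries of an age exchanged genotype together, 3 of 16 arrangements called at least as many genes as the real 6165, up to 9157 with P60 exchanged, and 16 are too few to exclude chance.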
